A study of Brassica rapa subsp. rapa with 9 samples.

How the data were processed

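Gene expression was measured in the swollen hypocotyls of turnip (Brassica rapa subsp. rapa, a red cultivar named Tsuda), the storage organ whose skin turns red with anthocyanin where light reaches it. Per the labels, organs were exposed to blue light, UV-A or UV-B for 24 hours or were kept in darkness, RNA came from a peeled surface layer of about 1 to 2 mm, and polyA RNA was purified on oligo(dT) cellulose after a Trizol extraction. Each of the 9 arrays carried 1 exposed sample labelled with Cy3 and 1 dark sample labelled with Cy5, with 3 arrays per light and no dye swap. Groups and replicate numbers were taken from the sample titles, because the free-text description names blue light for all 9 samples. Per the series' design text, the 3 replicates of a light were biological and each came from over 5 plants.

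Arrays were spotted with cDNA clones and labelled with a dendrimer kit (3DNA Array 900), per the labels. The deposited text file of each array holds foreground and background intensity values for both channels on a linear scale, as the authors' scanner software gave them. The scanner, its software and the pixel statistic are not given in the sources used here. An array had 6272 spots in 8 by 4 blocks of 14 by 14 spots, and 135 of them held no clone number. The deposited files also hold a weight of 0 or 1 per spot, a score without a stated meaning that was the same in all 9 files. Spots of weight 0 (972) were read as left out by the authors, and the 5300 spots of weight 1 were used.

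The authors also deposited a table of processed values on a log2 scale for the same arrays. Each of its columns had a mean of 0, and the column medians lay between -0.165 and 0.047. Its normalization is not given in the sources used here. Set against the scanner values of the same array, its columns correlated at -0.963 to -0.854 with log2(light/dark), so that it runs as dark over light, and its sign was turned before use. This direction opposes the one printed here. Its 2506 probes shared with the tested ones served as an alternative source of values. Per the series' design text, the authors made 3 further arrays of dark RNA in both dyes to correct gene-specific dye bias, which are not analysed here. Each log2(light/dark) below therefore includes any dye bias of its probe, while a difference between lights does not, since all arrays had the same dye orientation.

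Background was corrected with limma's normexp method (offset 50) and log ratios were normalized within each array by loess over all spots of weight 1, in R 4.3.3 with limma 3.58.1. Figures were drawn in Python 3.11.15 with matplotlib 3.10.9. Spots of a probe were averaged. A probe was kept where the foreground of at least 1 channel was 1.5 times the background in at least 3 arrays, a filter that removed no probe. The 2507 tested probes comprised 2107 with the name of an Arabidopsis gene (996 names), 123 without a match and 277 named after genes of other organisms. Names are the best sequence matches in the deposited annotation. They could not be matched to the turnip gene table used here, so no turnip coordinates are given. A total of 352 names were carried by over 1 probe, up to 33, and the probe with the highest mean signal over the 9 arrays represents its name. Duplicate spots correlated at 0.61 to 0.956 within an array.

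One limma model held a mean per light over all 9 arrays with 1 shared estimate of the spread. Each light was tested against dark as a mean log2(light/dark) against 0, each pair of lights as a difference of means, and the 3 lights together by a moderated F test. Tests were two-sided, and a probe passed at a Benjamini-Hochberg adjusted p under 0.05. In the tests of light against dark, the spread of the dark samples enters through the ratios and is not estimated by itself. Positive values always mean more RNA in the light named first, relative to the dark sample of the same array. Between lights, a value is a difference of such ratios. Adjusted p-values are limma's throughout, and n is 3 arrays per light. The number of arrays limits the precision.

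Gene lists were tested with limma's camera (preset correlation between genes of 0.01) on the 996 representative probes, adjusted over the 23 lists with at least 3 measured genes. Of the lists, 29 were fixed as name patterns before the data were examined, and 10 were added from the annotation alone, before any expression value was read. They are called added lists. Camera with an estimated correlation and fry, a rotation test of each list by itself, served as alternatives. Fixed lists with fewer than 3 measured genes were not tested.

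Named genes followed a rule fixed before the data were examined. For each comparison it took the 5 named probes with the largest rise and the 5 with the largest fall among those that passed with all arrays on one side of 0, or with no overlap of 2 lights. It also took, per list, the 2 passing members with the largest change, or the brightest member where none passed. Enzymes of the phenylpropanoid and flavonoid pathways, their regulators and light receptors were always named where measured. About 20 to 30 of these genes per comparison are given. Genes with many probes, called in opposite directions or shared by lights (MT2A and CWLP) were chosen after their values were seen, as were those that complete a short count of a list (CYP98A3 and ATOMT1 in UV-A, SAG21 and FAD6 in UV-B, RCI2B in UV-B against blue).

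Arrays of one number deviated together: the correlation across probes of their deviations from the light means was 0.105 to 0.622 for the same number and -0.625 to 0.059 for different numbers. Replicate numbers were therefore taken to pair the samples, and a fit with the number as a block is given where it changes the call of a representative probe in the text or moves the total of a comparison by over 1.5 times. Whether arrays of one number shared a dark RNA is not given in the sources used here. The whole procedure was tested on simulated data with the 2507 probes, 100 of them changed by 1 and 100 by 2 on the log2 scale in UV-B, and noise shared within numbers. In 10 simulations the UV-B against dark test recovered 33.2% and 86.3% of them with 5.16% false calls, and the UV-B against blue test recovered 4.8% and 58.2% with 1.56% false calls. With the block, false calls were 12.7% for UV-B against dark and 3.91% for UV-B against blue. The block takes the spread between numbers out of the error of a light's mean. Its p-values for light against dark therefore tend to be too small, and its calls there are no firmer than those without it. Blue light, simulated without change, had a mean of 0.3 false calls with the block, and UV-A against dark was not looked at in these simulations. For lists, camera called a list of 27 genes moved by 1 in 10 of 10 simulations of UV-B against dark, and no other list. Fry called it in 10 of 10 too, and called other lists 3 times. The simulated noise was independent between genes, so false list calls from correlated genes could not appear.

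Alternatives were no background correction, plain subtraction, median centring in place of loess, print-tip loess, scaling between arrays, Aquantile normalization, no filter and a strict filter on dim probes, ignored spot weights, the authors' processed values, the replicate block, each comparison on its own arrays, each array left out in turn, array weights, duplicate spots kept apart and a size threshold of 1 on the log2 scale. An alternative without the 3 arrays numbered 3, and one with the authors' values and the block together, were added after seeing the data.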

Results

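The study compared expression profiles of turnip swollen hypocotyls after blue light, UV-A or UV-B with those of organs kept in darkness. It holds 9 arrays, 3 per light, each with 1 exposed and 1 dark sample. The median over spots of the ratio of foreground to background in the light channel was 3.57 on UV-B replicate 1 and 65.8 on UV-A replicate 2, the lowest and highest of the 9. In the dark channel this ratio lay between 9.17 and 36.9. The light channel was above background for 75.3% of the probes on UV-B replicate 1 and for 99.9% on UV-A replicate 3. Log ratios of replicate arrays correlated across probes at 0.379 to 0.388 in blue light, 0.415 to 0.684 in UV-A and 0.573 to 0.772 in UV-B, where probes are not independent replicates. Spots without a clone were above background for 3.7% to 8.15% of 135 spots on the arrays numbered 1 and 2, and for at least 99.3% on the 3 arrays numbered 3. Of the 91 probes that represent the named genes, 24 had a saturated spot on at least 1 array, so the sizes of their changes are not exact. In the text these are AT2G01520, AT2G36160, AT1G71940, AT3G60245, AT4G27830, ARAC9, ATCDC5, ATHCHIB, CHS, DRM1, FAB1, PIP1B, PIP3, PR4, PRXR1, RD21, SAG21 and SAR1. Genes below carry the names of their best Arabidopsis matches.

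**Figure D1:**
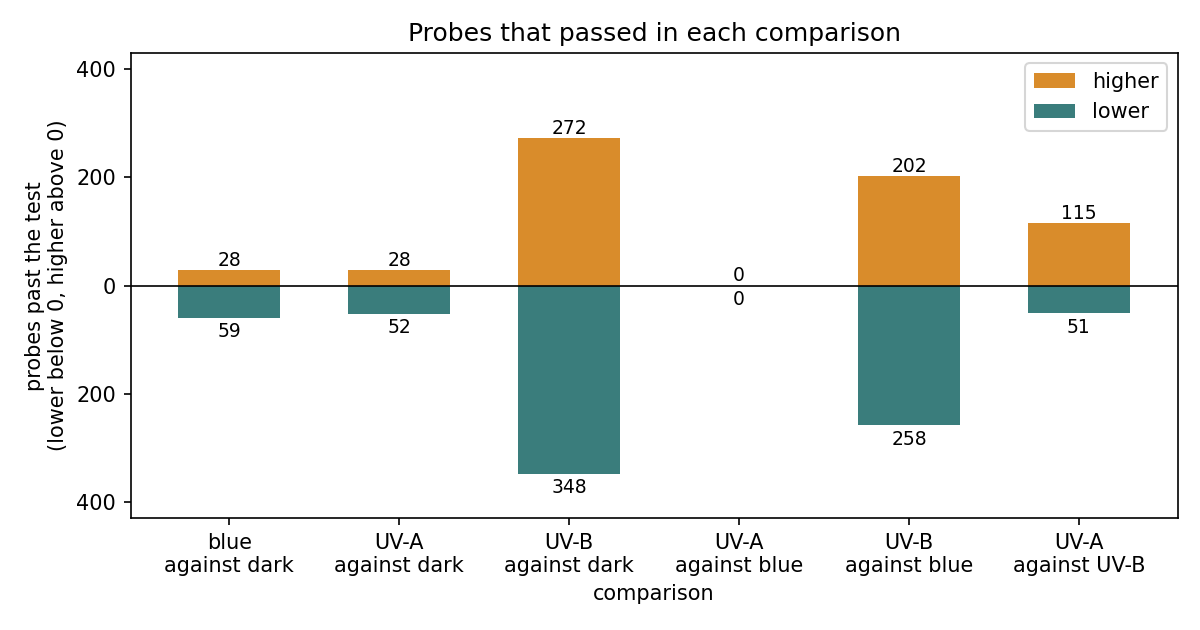
Number of probes, of 2507 tested, that passed the test in each of the 6 comparisons, with those higher in the light named first drawn above 0 and those lower drawn below 0. UV-B against dark has 272 higher and 348 lower, and UV-A against blue has 0.

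Blue light against darkness was a direct comparison on each array. AT5G66040, a protein of unknown function in the annotation, rose 8.5-fold (log2 3.09 ± 0.549 SE, n = 3, adjusted p = 0.0283), and RD21, a dehydration-responsive cysteine protease, rose 7.46-fold (log2 2.90 ± 0.594, adjusted p = 0.0358). The zinc-finger gene ZML1 rose by 1.92 ± 0.34 (log2), the annotated electron transporter AT1G76080 by 1.82 ± 0.449, and LHCB2.1, which encodes a chlorophyll-binding antenna protein, by 1.24 ± 0.304. MAM1, a methylthioalkylmalate synthase of glucosinolate chain elongation, fell by 2.75 ± 0.581 (log2, adjusted p = 0.0361), and AT2G43100, a subunit of isopropylmalate isomerase, fell by 2.17 ± 0.355 (log2, adjusted p = 0.0283). AT3G44735, of unknown function in the annotation, fell by 2.79 ± 0.544 on the log2 scale. The other probe of LHCB2.1 had a log2 of 0.25 and did not pass, the other RD21 probe rose and 1 of 2 other MAM1 probes fell.

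By group, the 10 measured genes of the ribosomal protein list had a mean log2 of -0.56, and 1 of them, ARP1, fell (by 1.30 ± 0.279, adjusted p = 0.0361). Adjusted over the list alone, 4 fell. The wider added list of 74 structural constituents of the ribosome had a mean of -0.55 and 13 positive values. In it 9 genes fell and none rose, among them AT3G60245 (fell by 1.76 ± 0.359, log2, with 3 of its 10 other probes falling) and AT1G09690 (fell by 1.72 ± 0.412, log2). Adjusted over the list alone, 26 fell and 1 rose. Camera called both lists (adjusted p = 0.011 and 1.11e-10). With an estimated correlation neither was called (adjusted p = 0.469 and 0.0527), while fry called both (adjusted p = 0.0197 and 0.00223). The call of the first list was also lost without blue replicate 1 (adjusted p = 0.129). Of 4 measured flavonoid structural genes, none passed. CHS, chalcone synthase at the entry of the pathway, had a log2 of 1.41 ± 0.448 (adjusted p = 0.095), and F3H had 0.26 ± 0.3. With the replicate block CHS had adjusted p = 0.012, and 4 of its 7 probes rose and 1 fell. The block tends to make p-values against dark too small. LDOX had 0.39 ± 0.346, DFR 0.34 ± 0.534, PAL1 0.34 ± 0.273 and ATGSTF12 0.13 ± 0.282. Adjusted over the list alone, 1 of the 4 rose. The myrosinase cofactor gene ESP rose by 1.38 ± 0.296 (log2), 1 of 6 glucosinolate genes to pass (and 1 adjusted over the list alone), though its 2 other probes did not pass, and the peroxidase AT5G58390 fell by 1.38 ± 0.318, 1 of 27 oxidative stress genes to pass (and 1 adjusted over the list alone). Among 7 genes of the abscisic acid, cold and drought list RD21 rose and the others did not pass, with 2 rising when adjusted over the list alone (camera adjusted p = 0.197). PHOT1, a blue light receptor, had a log2 of -0.45 ± 0.319 and the UV-B receptor gene UVR8 had 0.19 ± 0.258, neither of which passed.

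Blue light had 28 probes higher and 59 lower than darkness at an adjusted p under 0.05 in limma. The total of 87 was 404 with the replicate block and 18 (12 higher and 6 lower) with the authors' processed values. It was 50 (8 higher and 42 lower), 19 (14 higher and 5 lower) and 0 (with 299 unadjusted) without blue replicates 1, 2 and 3, so the balance turned in the authors' values and without blue replicate 2. It also did so with the authors' values and block together (143 higher and 141 lower) and without UV-A replicate 1 (9 and 8). The total was 17, 26 and 23 without UV-A replicates 1, 2 and 3, and 14 without UV-B replicate 1. Of the 17 named genes called, the fits with fewer arrays kept 10, 6, 0, 4, 6, 7 and 3, in that order, and the authors' values kept 3, with an adjusted p of at most 0.115 for the others. LHCB2.1 lost its call with plain subtraction (0.112), median centring (0.0577), print-tip loess (0.0509) and the authors' values (0.099), and without any 1 array but UV-B replicate 3 (at most 0.281). AT1G76080 lost its own with plain subtraction (0.0636), print-tip loess (0.0732), ignored weights (0.0601) and the authors' values (0.0795), and in the same fits with fewer arrays (at most 0.333). Plain subtraction also ended the calls of AT5G58390, AT1G09690 and AT3G60245. Folds moved by over 1.5 times as well. Without blue replicate 3, AT5G66040 had a log2 of 2.07, RD21 2.00, AT1G76080 1.14 and AT3G44735 -1.80, without blue replicate 2 the first pair had 3.96 and 3.94, and without blue replicate 1 MAM1 had -3.56.

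UV-A against darkness gave rises in enzymes of flavonoid synthesis. F3H, flavanone 3-hydroxylase, rose 3.24-fold (log2 1.70 ± 0.3 SE, n = 3, adjusted p = 0.0138), with a per-array SD of 0.083, though its call was lost without UV-A replicate 1, 2 or 3 (adjusted p = 0.0763, 0.124 and 0.123). CHS rose 3.57-fold (log2 1.84 ± 0.448, adjusted p = 0.0482), and 6 of its 7 probes rose. DFR, dihydroflavonol reductase, had a log2 of 0.40 ± 0.534 and LDOX, anthocyanidin synthase, had 0.28 ± 0.346, neither of which passed. PAL1, phenylalanine ammonia-lyase at the entry of phenylpropanoid synthesis, had 0.98 ± 0.273 (adjusted p = 0.0737, or 0.0328 with the block). The dehydrin ERD14 rose by 1.86 ± 0.415 (log2) and the pathogenesis-related gene PR4 by 1.37 ± 0.268, where the other ERD14 probe rose too and the other PR4 probe had 0.78 and did not pass.

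**Figure D2:**
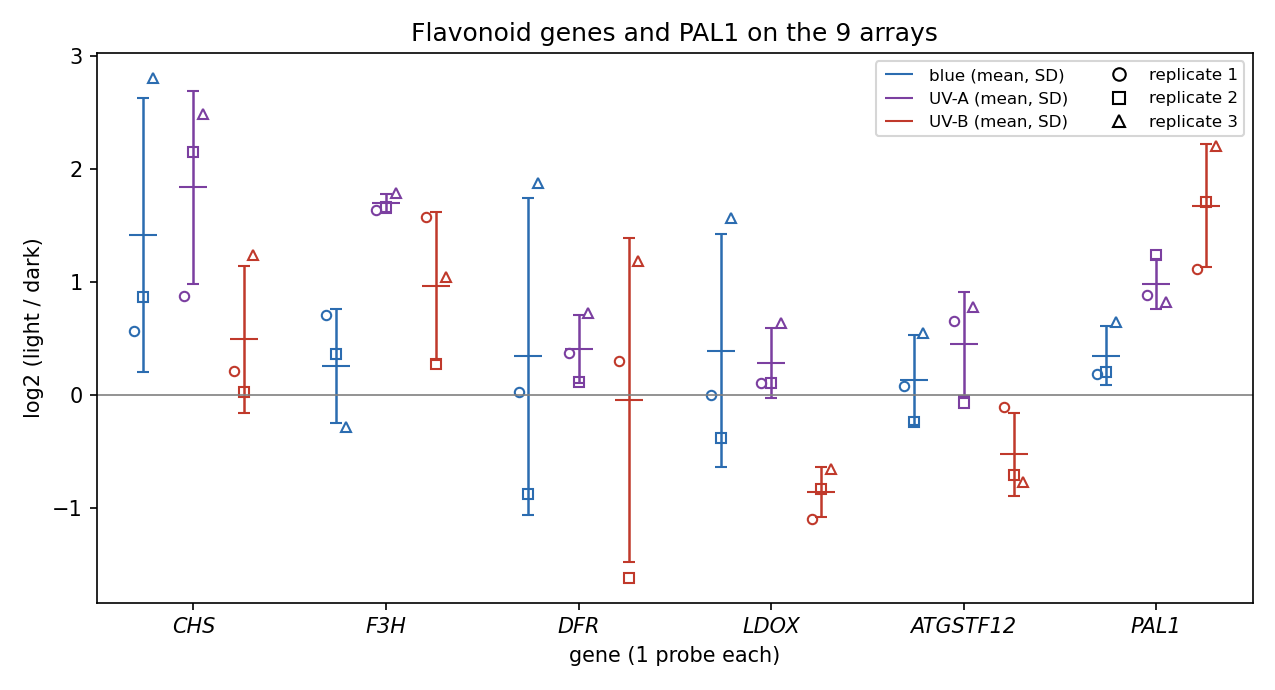
The log2 ratio of light over dark for 5 flavonoid genes and PAL1 on each of the 9 arrays, with 1 symbol per replicate number and the mean with its SD (n = 3) per light. F3H lies near 1.70 on all UV-A arrays, while CHS has an SD of 1.22 over the blue arrays.

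Of the 4 flavonoid structural genes, 2 rose in UV-A, and 2 when adjusted over the list alone. The list's mean log2 was 1.05 (camera adjusted p = 0.0241), but the call was lost with adjusted p = 0.299 with an estimated correlation, and also without UV-A replicate 3 (adjusted p = 0.0718) and in the authors' values (0.0534). The same list with the anthocyanin-related transferase ATGSTF12 (log2 0.45 ± 0.282, not passed) had a mean of 0.93, and the added phenylpropanoid and lignin list, PAL1, CYP98A3 and ATOMT1, had a mean of 0.88. No gene of the latter passed over all probes, and 3 rose when adjusted over the list alone. Both had camera adjusted p = 0.0241 and adjusted p = 0.299 with an estimated correlation, and both calls were lost without UV-A replicate 3 (adjusted p = 0.0718 and 0.0695). The call of the latter was lost without UV-A replicate 2 too (adjusted p = 0.0601). The 74 ribosome constituents had a mean of -0.37 and 1 gene that fell, AT5G03850 (by 1.15 ± 0.235, log2), with 1 falling when adjusted over the list alone. The 10 genes of the ribosomal protein list had -0.38 with none passed and 2 falling when adjusted over the list alone. Their camera adjusted p = 2.99e-07 and 0.0241 became adjusted p = 0.138 and 0.299 with an estimated correlation. The call of the 10 genes was lost without UV-A replicates 1 and 3 (adjusted p = 0.0655 and 0.121). The added list of 23 genes of cell wall loosening and synthesis had -0.32 with no gene passed (camera adjusted p = 0.0241, adjusted p = 0.262 with an estimated correlation, 0.0764 without UV-A replicate 2 and 0.0695 without UV-A replicate 3). Print-tip loess ended the UV-A calls of all these lists but the 74 ribosome constituents, with adjusted p = 0.0588 for both flavonoid lists and the phenylpropanoid and lignin list, 0.0592 for the cell wall list and 0.0615 for the 10 ribosomal protein genes. The authors' values ended the last 3 of these calls too (0.0928, 0.103 and 0.0534), and the strict filter that of the cell wall list (0.12). Of all these lists, fry called only the 74 ribosome constituents (adjusted p = 0.0221), with adjusted p = 0.0552 to 0.0587 for the others.

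Outside these lists, AT5G66040 rose 6.18-fold (log2 2.63 ± 0.549, adjusted p = 0.027) in UV-A, and AT4G01130, an ester hydrolase in the annotation, rose 4.29-fold (log2 2.1 ± 0.272, adjusted p = 0.00371). MAM1 fell by 3.40 ± 0.581 (log2, adjusted p = 0.0126), AT2G43100 by 2.64 ± 0.355 and AT2G39960, an annotated signal peptidase, by 2.15 ± 0.435. The tubulin gene TUA5 fell by 1.03 ± 0.232 (log2), while none of its 8 other probes passed, with log2 values between -1.45 and 0.40. UVR8 had 0.06 ± 0.258 and PHOT1 had -0.12 ± 0.319, neither of which passed. UV-A had 28 probes higher and 52 lower than darkness, and the total of 80 was 279 with the block, and 213 higher and 210 lower with the authors' values and block together. It was 23, 0 (with 332 unadjusted) and 2 without UV-A replicates 1, 2 and 3, 133 without blue replicate 3 and 49 without UV-B replicate 1. Of the 14 named genes called, 4, 0, 0, 14 and 10 kept their call in these fits. CHS lost its call without any 1 of blue replicates 1 and 2, the 3 UV-A replicates and UV-B replicates 1 and 2, with an adjusted p of at most 0.267. It also lost it with plain subtraction (0.056), with print-tip loess (0.0564) and with the spot weights ignored (0.0582).

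UV-B against darkness gave the highest count of the 3 lights, and defence genes were among those with the largest rises. PR4 rose 15.6-fold (log2 3.96 ± 0.268 SE, n = 3, adjusted p = 7.56e-06), while its other probe had -0.52 and did not pass. The basic chitinase ATHCHIB rose 12.4-fold (log2 3.63 ± 0.45, adjusted p = 0.000221), as did 3 of its 4 other probes. ATCDC5, a DNA-binding protein in the annotation, rose 22.8-fold (log2 4.51 ± 0.299, adjusted p = 7.56e-06) and AT4G13430, a subunit of isopropylmalate isomerase, rose 8-fold (log2 3.00 ± 0.377). PAL1 rose by 1.67 ± 0.273 (log2, adjusted p = 0.00132) and F3H by 0.97 ± 0.3 (adjusted p = 0.0356). CHS had 0.49 ± 0.448 on its brightest probe, which did not pass, while 4 of its 6 other probes rose. LDOX had -0.86 ± 0.346 and did not pass (adjusted p = 0.0916), but it fell with the block (adjusted p = 0.0331), in the authors' values (0.039) and with print-tip loess (0.045). With the block 1 of the 2 other LDOX probes rose. DFR had -0.05 ± 0.534, ATGSTF12 -0.53 ± 0.282, UVR8 0.01 ± 0.258 and PHOT1 0.37 ± 0.319, none of which passed. Of the 4 flavonoid structural genes 1 rose, and 1 when adjusted over the list alone, with a mean of 0.14 (camera adjusted p = 0.928).

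Among the falls in UV-B, AT2G01520, an unknown protein in the annotation, fell by 4.51 ± 0.377 (log2, adjusted p = 1.91e-05), and 4 of its 8 other probes fell. Its dark signal was saturated in 2 of 2 spots on UV-B replicate 3 and in 1 on UV-B replicate 2. The small GTPase gene ARAC9 fell by 3.74 ± 0.416 (log2), the glycosidase AT4G27830 fell by 3.61 ± 0.303, and RALFL22, a signalling peptide, fell by 3.13 ± 0.395. The peroxidase PRXR1 fell by 3.04 ± 0.366 (log2, adjusted p = 0.000189), as did 23 of its 28 other probes. The aquaporin gene PIP3 fell by 2.09 ± 0.327 (log2) and PIP1B, another, by 1.75 ± 0.249. They were the 2 measured genes of the root and storage organ list, too few for a test. EXGT-A1, a xyloglucan endotransferase of the cell wall, fell by 2.79 ± 0.537 (log2), although its 2 other probes had -0.02 and 0.08 and did not pass. MAM1 fell by 2.59 ± 0.581 and CYP83A1, a P450 of glucosinolate synthesis, by 2.29 ± 0.394 (log2), with 5 of the 18 other CYP83A1 probes falling and 1 rising. Glucosinolate genes moved both ways in UV-B. In the added list of 10 glucosinolate enzymes 3 rose and 4 fell. In the glucosinolate and myrosinase list of 6 genes 1 rose and 2 fell.

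**Figure D3:**
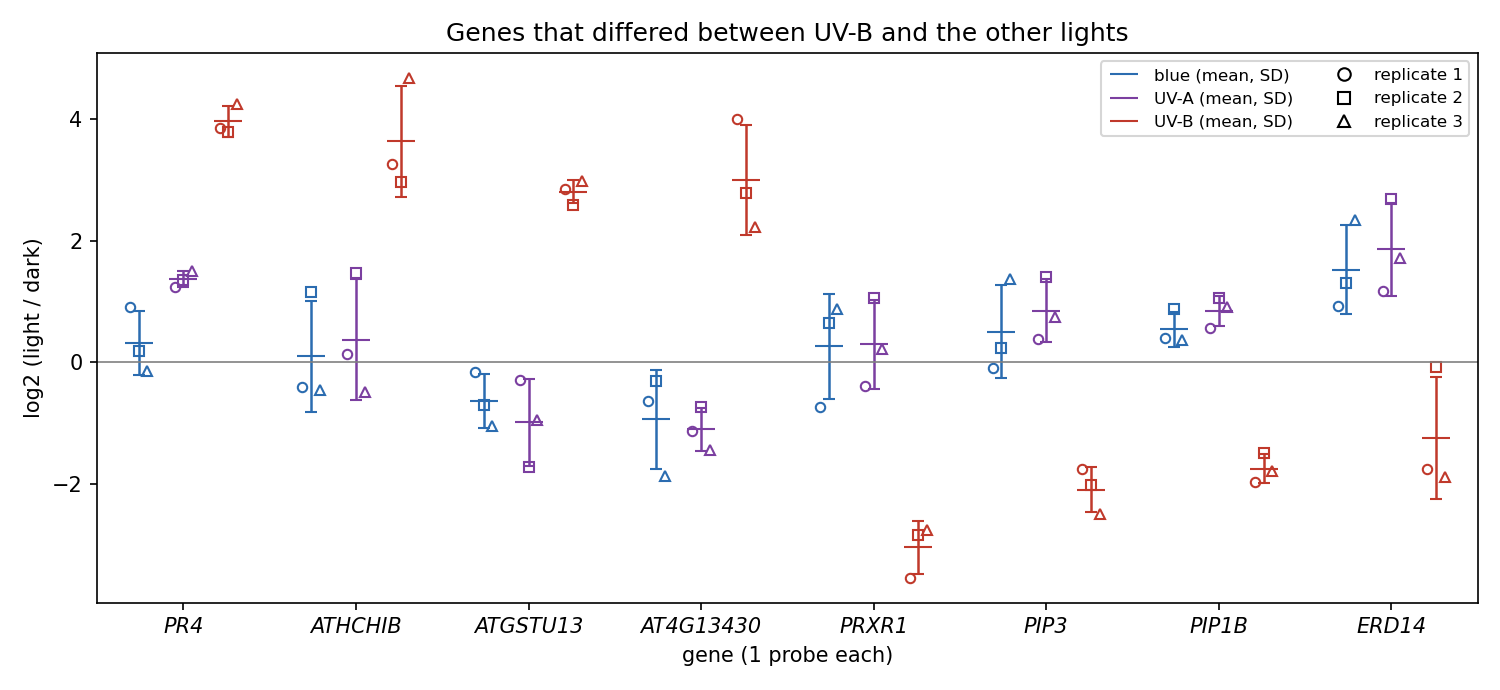
The log2 ratio of light over dark for 8 genes on each of the 9 arrays, with 1 symbol per replicate number and the mean with its SD (n = 3) per light. In UV-B the PR4 mean is 3.96 and the PRXR1 mean is -3.04, and for each gene the 3 UV-B arrays lie apart from the blue and UV-A arrays.

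By group, 2 of 6 defence genes rose in UV-B, PR4 and ATHCHIB, and 2 when adjusted over the list alone. Of 27 oxidative stress genes, 6 rose and PRXR1 fell, with 7 rising and 1 falling when adjusted over the list alone. Those that rose included the glutathione transferase ATGSTU13 (log2 2.81, adjusted p = 0.000114). Of 25 proteasome and ubiquitin genes, 5 rose and 1 fell, among them the ubiquitin ligase AT5G63780 (log2 2.43) and the ubiquitin protease UBP24 (-1.89), with 6 and 1 when adjusted over the list alone. Of 20 cytoskeleton and translation genes, 6 rose and 2 fell, including the elongation factor AT1G07920 (1.63) and the tubulin TUB6 (-1.92), with the same counts adjusted over the list alone. Of 7 abscisic acid, cold and drought genes, RCI2B (-1.49) and ERD14 (-1.24) fell, and 2 fell when adjusted over the list alone. Of 4 dark-induced and senescence genes, SAG21 (0.88) rose while DRM1 (-1.59) and DIN11 (-1.31) fell, as did 5 of 10 and 4 of 24 of their other probes, with 1 and 3 adjusted over the list alone. Of 6 sugar and starch genes, the trehalose-6-phosphate synthase ATTPS1 (1.38) rose and SEX1 (-1.65), a gene of starch breakdown, fell, although 1 of the 4 other SEX1 probes rose, with the same counts adjusted over the list alone. In the added fatty acid list, 3 of 5 genes fell, the desaturases ADS2 (-2.22) and FAD6 (-1.20) and the synthase FAB1 (-1.59). Of 74 ribosome constituents 3 rose and 3 fell, with a mean of -0.004 and a median of 0.05. Camera called no list in UV-B, with adjusted p = 0.52 for defence, 0.582 for oxidative stress and 0.301 for proteasome and ubiquitin. For each of these, fry, which tests a list by itself, had an adjusted p of 0.00449, 0.0399 and 0.00467. Fry also called further lists, among them the cytoskeleton and translation reference genes (adjusted p = 0.0198), so its calls were not particular to stress lists. Its smallest adjusted p was 0.000474, for the dark-induced and senescence list (mean log2 -0.66). In the simulations fry also called lists that were not moved.

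UV-B had 272 probes higher and 348 lower than darkness. This balance turned in the authors' values (418 higher and 344 lower), in these with the block (589 and 480) and with the strict filter (273 and 272). The total of 620 was 329 without UV-B replicate 1 and 271 without UV-B replicate 3, where 30 and 26 of the 40 named calls were kept. Both fits lost the calls of F3H, ERD14, RCI2B and FAB1, and the fit without UV-B replicate 3 also lost those of MAM1, DRM1, DIN11 and SEX1. The highest adjusted p among these was 0.278, for ERD14, and 0.0964, for DRM1, among the last 4. F3H also lost its call with median centring (0.0535) and scaling (0.0633), and ERD14 with ignored weights (0.0531). Folds moved by over 1.5 times for MAM1 without UV-B replicate 3 (log2 -1.79), TUB6 without UV-B replicate 2 (-2.62) and EXGT-A1 without UV-B replicate 1 (-3.53). F3H and ERD14 were lost as well without UV-A replicate 3, F3H also without UV-A replicate 1, ERD14 also without UV-A replicate 1 and blue replicates 1 and 2, and DIN11 also without UV-B replicate 2.

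UV-A against blue, a comparison through the dark channel in which dye bias cancels, gave no passing probe in limma. A total of 80 probes had an unadjusted p under 0.05, and the smallest adjusted p was 0.952. With the replicate block the count was 0 too, with 180 unadjusted. F3H was 2.71-fold higher in UV-A by its mean (log2 1.44 ± 0.425 SE, n = 3 per light, adjusted p = 0.952), and its 3 UV-A values lay above all blue values, an absence of overlap that chance gives for 10% of probes. CHS had 0.42 ± 0.633, with all 7 of its probes between 0.42 and 2.69, and PAL1 had 0.64 ± 0.386. DFR had 0.06 ± 0.755, LDOX -0.11 ± 0.489, ATGSTF12 0.32 ± 0.399, UVR8 -0.13 ± 0.365 and PHOT1 0.33 ± 0.451. No list was called, and the flavonoid list of 4 genes had a mean of 0.45 (camera adjusted p = 0.381), with 1 rising when adjusted over the list alone. The median absolute log2 over all probes was 0.34.

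UV-B against blue differed in 460 probes, 202 higher and 258 lower in UV-B. In the authors' values (312 and 269), in these with the block (522 and 415) and with the strict filter (216 and 212) more were higher than lower. AT4G13430 was 15.3-fold higher in UV-B (log2 3.94 ± 0.533 SE, n = 3 per light, adjusted p = 0.000942), PR4 was 12.5-fold higher (3.64 ± 0.378, adjusted p = 0.000194) and ATHCHIB was 11.6-fold higher (3.53 ± 0.636, adjusted p = 0.00456). The other PR4 probe had not risen in UV-B against darkness. ATGSTU13 was higher by 3.45 ± 0.432, CYP81F4, a P450, by 2.00 ± 0.456, and PAL1 by 1.33 ± 0.386 (adjusted p = 0.0349). AT2G01520 was lower too (adjusted p = 0.000212), but its light signal was saturated on all 3 blue arrays, so no exact size can be given. The light signal there was at least 21-fold that of the UV-B arrays, with no normalization between arrays. The median light foreground was 2096 to 4593 on the blue arrays and 1178 to 2665 on the UV-B arrays, so this fold includes array brightness. AT4G27830 was lower at -4.52 ± 0.429, the glycosidase AT5G42100 at -4.31 ± 0.444, ARAC9 at -4.15 ± 0.589, RALFL22 at -3.95 ± 0.559 and PRXR1 at -3.30 ± 0.518. PIP3 was lower at -2.59 ± 0.463 and PIP1B at -2.29 ± 0.353. Of the flavonoid genes none of 4 passed, with CHS at -0.92 ± 0.633, F3H at 0.71 ± 0.425 and LDOX at -1.26 ± 0.489 (adjusted p = 0.094, or 0.0339 with the block), while 1 of the 2 other LDOX probes was higher. The CHS value was the lowest of its 7 probes, which had a median of 0.23 and 4 positive values, so CHS had no clear direction. DFR had -0.38 ± 0.755, ATGSTF12 -0.66 ± 0.399, UVR8 -0.18 ± 0.365 and PHOT1 0.82 ± 0.451, none of which passed.

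In the abscisic acid, cold and drought list, 3 of 7 genes were lower in UV-B than in blue light and none higher, RD21 (-3.32 ± 0.84), ERD14 (-2.77 ± 0.587) and RCI2B (-1.82), and 3 when adjusted over the list alone. The list had a mean of -1.49 (camera adjusted p = 0.0382, adjusted p = 0.729 with an estimated correlation, 0.0591 without blue replicate 1, 0.129 without blue replicate 3 and 0.0902 without UV-B replicate 1). Fry had adjusted p = 0.026 for it. RD21 lost its call without blue replicates 1 and 3 and without UV-B replicates 1 and 2, and had a log2 of -4.35 without blue replicate 2 and -2.42 without blue replicate 3. Of the 74 ribosome constituents, 10 were higher and 2 lower in UV-B (7 and 2 adjusted over the list alone), with a mean of 0.54 (camera adjusted p = 0.00424, adjusted p = 0.729 with an estimated correlation, 0.00666 with fry). The 2 lower ones were AT2G36160 (-2.66 ± 0.45) and AT4G02230 (-3.05 ± 0.439). Among the others, defence had 2 of 6 higher and oxidative stress 5 of 27 higher and 1 lower, with 2, and with 6 and 1, adjusted over the list alone. Of all 996 representative probes, 87 were higher and 95 lower in UV-B than in blue light. The total of 460 was 723 with the block, and it was 235 without UV-B replicate 1, 218 without UV-B replicate 3 and 282 without blue replicate 3, which kept 24, 23 and 24 of the 35 named calls. PAL1 lost its call without blue replicates 1 and 2, UV-A replicates 1 and 3 and UV-B replicates 2 and 3, with an adjusted p of at most 0.11, and CYP81F4 without UV-B replicate 3 (0.0527).

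**Figure D4:**
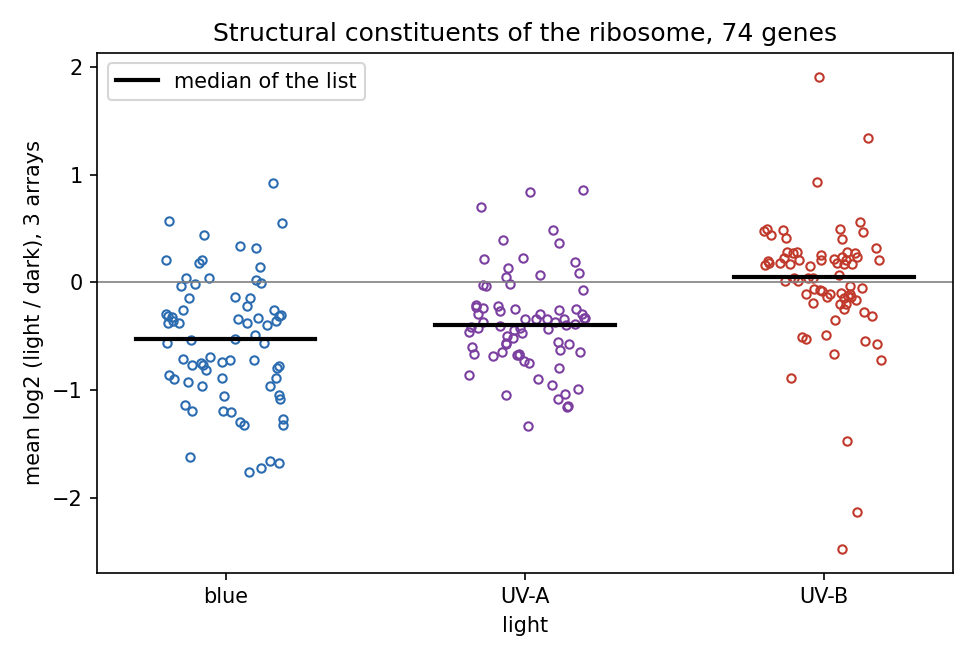
The mean log2 ratio of light over dark (3 arrays) for each of 74 structural constituents of the ribosome in each light, with the median of the list as a bar. The medians are -0.53 in blue light, -0.39 in UV-A and 0.05 in UV-B.

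UV-A against UV-B differed in 166 probes, 115 higher and 51 lower in UV-A. AT2G01520 was higher in UV-A (adjusted p = 0.000266), with its light signal saturated in 2 of 2 spots on UV-A replicate 3 and in 1 on UV-A replicate 1. ARAC9 was higher by 4.30 ± 0.589 (log2 ± SE, n = 3 per light) and AT4G27830 by 4.27 ± 0.429. PRXR1 was higher by 3.34 ± 0.518, ERD14 by 3.10 ± 0.587, PIP3 by 2.94 ± 0.463 and PIP1B by 2.59 ± 0.353. SAR1, a synaptobrevin-related gene, was higher by 3.50 ± 0.437, while its 2 other probes had -0.58 and -0.50 and did not pass. AT4G13430 was lower in UV-A at -4.10 ± 0.533 (log2, adjusted p = 0.000917), ATCDC5 at -3.88 ± 0.423, ATGSTU13 at -3.79 ± 0.432, ATHCHIB at -3.26 ± 0.636, the potassium transporter KUP5 at -3.10 ± 0.518 and PR4 at -2.59 ± 0.378. By its values against dark given above, the other PR4 probe lay the other way, higher in UV-A than in UV-B. For flavonoid enzymes, CHS had 1.35 ± 0.633 (adjusted p = 0.217, or 0.0459 with the block, where 5 of its 7 probes were higher in UV-A) and F3H had 0.73 ± 0.425, and PAL1 had -0.69 ± 0.386, none of which passed. Nor did DFR (0.45 ± 0.755), LDOX (1.15 ± 0.489), ATGSTF12 (0.98 ± 0.399), UVR8 (0.05 ± 0.365) or PHOT1 (-0.49 ± 0.451).

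In UV-A relative to UV-B, 2 of the 7 abscisic acid, cold and drought genes were higher and none lower, ERD14 and RCI2B (1.73 ± 0.462), with 3 adjusted over the list alone. The list's mean was 1.27 (camera adjusted p = 0.025, adjusted p = 0.7 with an estimated correlation, 0.0764 with fry, 0.088 without UV-A replicate 3 and 0.0646 without UV-B replicate 1). The 74 ribosome constituents had a mean of -0.36 with 2 higher and 1 lower, and the same counts adjusted over the list alone (camera adjusted p = 0.025, adjusted p = 0.7 with an estimated correlation, 0.0488 with fry, 0.0718 without UV-A replicate 1, 0.0817 without UV-B replicate 3 and 0.147 with the strict filter). Its 2 higher genes, AT2G36160 (2.86 ± 0.45) and AT4G02230 (2.62 ± 0.439), went against the sign of the list. The total of 166 was 378 with the block and 260 in the authors' values, and the authors' values with the block turned the balance (304 higher and 319 lower). It was 95 without UV-A replicate 1, 75 without UV-A replicate 3, 97 without UV-B replicate 1, 99 without UV-B replicate 3 and 278 without blue replicate 3, and of the 24 named calls 19, 17, 18, 19 and 24 were kept. ATHCHIB lost its call without UV-A replicate 3. RCI2B lost its call without blue replicates 1 and 2, each of the 3 UV-A replicates and UV-B replicates 1 and 3 in turn.

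Across the 3 lights, 257 probes differed by limma's F test, and 546 with the block. The count was 160 without UV-A replicate 1, 97 without UV-B replicate 1 and 103 without UV-B replicate 3. Of the probes that rose in blue light, 7 rose in UV-A too, and 20 fell in both. ZML1, the metallothionein MT2A and AT5G66040 were among the former. UV-A and UV-B shared 12 higher and 30 lower probes, and blue light and UV-B shared 2 higher and 16 lower. Noise shared by arrays of one number can make such overlaps too. In 100 simulations of unchanged groups with this noise, set up after the overlaps were seen, as many probes with the highest or lowest t values shared a mean of 2.08 and 9.86 for blue light and UV-A, 8.02 and 15.8 for UV-A and UV-B, and 11.4 and 25.4 for blue light and UV-B. The number shared by UV-A and UV-B among the higher probes was reached in 7 of them, and the others of the first 2 pairs in none. A total of 14 probes fell in all 3 lights, including MAM1, AT2G43100, AT1G71940 and the cell wall protein gene CWLP. Across the 2507 probes, which are not independent replicates, the mean changes in blue light and UV-A correlated at r = 0.713 (rho = 0.676), those in UV-A and UV-B at r = 0.252 (rho = 0.227) and those in blue light and UV-B at r = -0.017 (rho = -0.063). Simulated unchanged groups with shared noise gave r of 0.557, 0.159 and 0.282, with covariances of 0.082, 0.021 and 0.051 where the data had 0.341, 0.176 and -0.012. Leaving out each array in turn gave a jackknife SE of 0.161, 0.17 and 0.113 for these r of the data. The jackknife ran over the arrays of all 3 lights, but those of the light outside a pair cannot move its r. Its SE is therefore only a rough guide. By it, the r of the first 2 pairs lay within 1 SE of the simulated values, for blue light and UV-A only narrowly. That comparison cannot decide whether the r of blue light and UV-A exceeded the simulated one. The covariances of the first 2 pairs were above the simulated ones, and no SE is given for them.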

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

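The tests of a batch of the arrays numbered 3, of a wider scale of the UV-B log ratios and of the 36 partitions with the block fitted were chosen only after the results they concern were seen. Probes called in opposite directions in a pair of lights, with a passing test of the difference itself, stood out as follows. MBP1 (probe 1790), a myrosinase-binding protein, had a log2 of 1.24 in blue light and -1.09 in UV-B, a difference of -2.33 (adjusted p = 0.00456). AT5G42100 (probe 2488) had 1.56 in blue light and -2.75 in UV-B, a difference of -4.31 (adjusted p = 0.000194). AT3G45030 (probe 2668), a ribosome constituent, had -1.26 in blue light and 0.92 in UV-B, a difference of 2.17 (adjusted p = 0.00622). ATGSTF3 (probe 1181), a glutathione transferase, had -1.37 in UV-A and 2.86 in UV-B, a difference of -4.22 (adjusted p = 0.000268). The brightest probes of 3 of these genes, other than those named, were not called in opposite directions: MBP1 had 0.67 in blue light, AT3G45030 had -0.31 in blue light and -0.27 in UV-B, and ATGSTF3 had -0.48 in UV-A, none of which passed. Nor were any of the 4 other AT5G42100 probes. Both ERD14 probes were called higher in UV-A and lower in UV-B, with differences of 3.10 (probe 1619, adjusted p = 0.00737) and 3.50 (probe 2397, adjusted p = 0.00168).

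The change from darkness differed between lights in 460 probes for UV-B and blue light and in 166 for UV-A and UV-B. Among the 10 splits of the 6 arrays in each case, 1 split, the real one, gave as many, and the highest other gave 0. For UV-A and blue light all 10 of 10 splits gave 0. For each light against darkness, 1 of 4 patterns, the real one with 87, 80 or 620 probes, gave as many when light and dark were exchanged on 1 array, and the highest other gave 0. These splits are too few for a share under 0.05. With the replicate block, the real splits for UV-B and blue light and for UV-A and UV-B gave 723 and 378 probes. The other splits that part all 3 pairs, which mix lights, gave 0. Of 100 partitions drawn from the 280 of the 9 arrays, 3, the real one with 257 among them, gave at least that many probes in the F test. The highest other gave 367, and the partitions above the real one kept the 3 UV-B arrays together. The partition by replicate number gave 0. These partitions set the pairing by number aside. Of the 36 that hold 1 array of each number per group, with the block fitted, only 1, the real one with 546, gave as many. The only others with passing probes, 294, 317 and 420, also kept the UV-B arrays together and mixed blue light with UV-A. That share therefore speaks against 3 lights alike through UV-B, and not for a difference between blue light and UV-A. As the test was chosen after the partitions above were seen, it does not exclude chance.

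Spots outside the comparisons were bright on the 3 arrays numbered 3, where at least 99.5% of 838 spots of weight 0 with a clone and at least 99.3% of 135 spots without a clone were above background. On the other arrays the shares were 0.716% to 23.5% and 3.7% to 8.15%. Arrays of one number also deviated together from the means of their lights (correlations across probes of 0.105 to 0.622). Same-number arrays of numbers 1 and 2 had a mean correlation of 0.306, beside 0.38 for number 3. A batch of the arrays numbered 3 alone would give the former too, because deviations sum to 0 within a light. It would also correlate arrays of number 1 with those of number 2, but these pairs had -0.117 to 0.059. That argues against such a batch as the whole cause. A dark RNA shared by the arrays of one number cannot be told apart from plants, harvest or processing shared within a number. Over the 9 same-number pairs the covariance of dark with dark exceeded that of light with dark by 0.0816 (SE 0.0238), as a shared dark RNA needs. That of light with light exceeded it too, by 0.0213 (SE 0.0122), which a shared dark RNA alone would not give, but by under 2 SE. The 9 pairs share arrays and are not independent, so both SE are only a rough guide. Shared plants, harvest or processing stay open as well, since light with light exceeded light with dark in 7 of 9 pairs, short of the 8 set beforehand, and no biological explanation was tested.

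UV-B had 620 probes called against darkness, blue light 87 and UV-A 80. Against a lower signal of the UV-B arrays as the cause, the 835 brightest probes had 292 calls in UV-B, 10.4 times the higher of blue light (25) and UV-A (28). Against noise of the UV-B arrays, the lowest covariance of a pair of UV-B arrays was 0.734, above the highest of a pair of blue or UV-A arrays (0.387). A wider scale of the UV-B log ratios cannot be told apart from a larger response to UV-B, because scaling between arrays left 546 calls in UV-B, 1.58 times the higher of blue light (168) and UV-A (345), while a larger response would itself widen the scale. A larger response of the tissue to UV-B, the biological difference that the design names, stays open as a hypothesis.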

How the results depend on the processing

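The fits without the 3 arrays numbered 3, and with the authors' processed values and the replicate block together, were chosen after seeing the data, and the other alternatives before. Totals of passing probes are compared with those reported (87 for blue light, 80 for UV-A and 620 for UV-B against darkness, 0 for UV-A against blue, 460 for UV-B against blue, 166 for UV-A against UV-B and 257 for the F test), and where no cause is given the cause was not tested. Blue light against darkness had 49 with plain subtraction, 168 with scaling between arrays, 18 with the authors' values, 404 with the block, 218 with duplicate spots apart, 20 on its own arrays and 284 with the authors' values and block. UV-A against darkness had 345 with scaling, 279 with the block, 824 with array weights, 155 with duplicate spots apart and 423 with the authors' values and block. UV-B against darkness had 1030 with array weights and 1069 with the authors' values and block. UV-A against blue had 3 with scaling. UV-B against blue had 723 with the block, 692 with array weights, 293 on its own arrays and 937 with the authors' values and block. UV-A against UV-B had 252 with scaling, 260 with the authors' values, 378 with the block, 798 with array weights, 274 with duplicate spots apart and 623 with the authors' values and block. The F test had 546, 760, 454 and 745 with the block, array weights, duplicate spots apart and the authors' values and block. With fewer arrays, the fit without the arrays numbered 3 had 0, 32, 422, 0, 186, 81 and 91, in the order of the totals above, with 375 and 64 unadjusted at the zeros. Leaving out 1 array gave 0 (blue replicate 3, 299 unadjusted) to 102 (UV-B replicate 3) for blue light, with 50, 19, 17, 26, 23 and 14 without blue replicates 1 and 2, UV-A replicates 1, 2 and 3 and UV-B replicate 1. It gave 0 (UV-A replicate 2, 332 unadjusted) to 133 (blue replicate 3) for UV-A, with 23, 2 and 49 without UV-A replicates 1 and 3 and UV-B replicate 1, and 271 (UV-B replicate 3) to 737 (blue replicate 3) for UV-B, with 329 without UV-B replicate 1. Between lights it gave 0 in each fit for UV-A against blue (43 to 177 unadjusted), 218 (UV-B replicate 3) to 460 for UV-B against blue, with 235 and 282 without UV-B replicate 1 and blue replicate 3, and 75 (UV-A replicate 3) to 278 (blue replicate 3) for UV-A against UV-B, with 95, 97 and 99 without UV-A replicate 1 and UV-B replicates 1 and 3. For the F test it gave 97 (UV-B replicate 1) to 267, with 160 and 103 without UV-A replicate 1 and UV-B replicate 3. The share of higher calls moved from 32.2%, 35% and 43.9% for blue light, UV-A and UV-B against darkness to 66.7%, 45.4% and 54.9% in the authors' values, and from 69.3% to 56.9% for UV-A against UV-B. For UV-B against blue it moved from 43.9% to 53.7% in those values, or 50.5% with the strict filter, which gave 50.1% for UV-B. Print-tip loess gave 46.5% for UV-A. Without blue replicates 1 and 2 and UV-A replicate 1 the share in blue light was 16%, 73.7% and 52.9%. The authors' values with the block gave 50.4% for blue light and for UV-A, and 48.8% for UV-A against UV-B. The authors' values kept 14 of 87, 70 of 80, 545 of 620, 409 of 460 and 152 of 166 calls. Camera made 12 list calls. There were 0 with an estimated correlation, 22 with fry (6 of the 12 among them), 46 with all probes per gene (all 12), 9 with print-tip loess (7), 11 in the authors' values (8) and 8 (without UV-A replicate 3, with 6) to 15 with 1 array left out. Of 130 named calls none reversed, and 110 were kept in the authors' values, 130 with the block, 68 without the arrays numbered 3 and 85 (without UV-B replicate 1) to 115 with 1 array left out. Aquantile normalization and the lack of a filter moved nothing, so they test nothing. The mean against the median of the pixels, and slide or scan batches, were not run, as the files hold 1 statistic and no batch. Fits on own arrays give no F test, and lists were not run with array weights or duplicate spots apart.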

Other observations

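The test of probes picked on other arrays was chosen only after the result it concerns was seen, as were the genes named first, those with many probes. AT3G14210, an ester hydrolase in the annotation, had 28 probes, of which 22 fell and 1 rose in UV-B against darkness (median log2 -2.01). In blue light 1 of them fell and 1 rose, and in UV-A 1 fell. Against blue light 20 were lower in UV-B and none higher, and 13 were higher in UV-A than in UV-B, or 20 with the replicate block, which also had 3 rising in blue light and 2 in UV-B. AT1G54020, another annotated ester hydrolase, had 33 probes, of which 4 fell in blue light, 13 in UV-A and 19 in UV-B, where 1 rose. With the block 9 fell in blue light, and 12 were lower in UV-B than in blue light where 7 were without it. Their median log2 values were -0.43, -1.40 and -1.66. Of 12 probes of the myrosinase-binding protein gene MBP1, 5 fell in UV-B and 6 were lower in UV-B than in blue light, with a median of -1.97 for that difference, and 1 rose in blue light, or 3 with the block.

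The symbol ACO1, which the file does not tell apart between an ethylene-forming oxidase and an aconitase, had 9 probes. In UV-B 4 of them rose (median log2 1.52), and 4 were higher in UV-B than in blue light (median 2.2), while with the replicate block 7 rose and all 9 were higher than in blue light. Its brightest probe did not pass against blue light without the block (adjusted p = 0.0543) and passed with it (0.0291). In UV-A 1 was lower than in UV-B, or 8 with the block. In blue light and UV-A none passed, with medians of -0.68 and -0.80, and 1 fell in each with the block. JR1, named after jasmonate response, had 7 probes with a median of 1.43 in blue light, where none passed in limma and 6 rose with the block, as did 3 in UV-A. In UV-B 1 rose and 1 fell, or 2 fell with the block. Calls against dark with the block tend to be too many. Of 8 metallothionein MT2A probes, 1 rose in blue light and 1 in UV-A, with medians of 0.62 and 0.93, and none passed in UV-B (median 0.02). With the block 2 rose in blue light, 4 rose in UV-A and 1 fell in UV-B. Of 31 probes of the peptidase inhibitor AT1G72290, 6 rose and 2 fell in UV-B, so probes of one name did not always move together.

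Each log ratio of light over dark includes the dye bias of its probe, which could mimic a change shared by lights. For the 7 probes higher in both blue light and UV-A (AT5G66040, AT4G11320, AT3G57520 with a pair of probes, MT2A, AT2G39310 and ZML1), dye bias as the whole cause would give the same log ratio in UV-B. The UV-B value over the mean of blue light and UV-A had a median of 0.14 and ran from -0.138 to 0.471. Picking the probes on the same arrays raises their blue and UV-A values, so this ratio excludes nothing. For as many probes picked without the arrays of one number, the UV-B median over that of blue light and UV-A on those arrays was 0.878, -1.49 and 0.338 for numbers 1, 2 and 3. Dye bias therefore cannot be told apart from a response shared by blue light and UV-A, since these ratios lie on both sides of the bounds set. For the 14 probes lower in all 3 lights, among them MAM1, AT1G54020, AT2G43100 and CWLP, dye bias cannot be told apart from a response to light, because no source states whether the authors' values hold the dye correction. Those values kept at least 0.662 of the log ratio of each probe, with a median share of 0.844.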
